A study of Homo sapiens with 4 samples.

How the data were processed

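Single-cell RNA libraries were made from PANC-1 tumours grown under the skin of nude mice, with 1 library each for control, agrimoniin, erlotinib and the combination of agrimoniin and erlotinib. Per the labels' protocols, tumours were digested with collagenase II, passed through a strainer and loaded for a target of 8000 cells with a Chromium 3 prime kit. Per the submitters' processing notes, the authors used Cell Ranger with the builds hg38 and mm10, and the version is not given in the sources used here. The deposited values are UMI counts per gene and barcode, not normalised, over 68886 features, of which 36601 are human and 32285 are mouse. How the authors chose the deposited barcodes is not given in the sources used here. Barcodes had 27 bases in 3 blocks of 9, which is not the barcode layout of the named kit, so the platform and the way barcodes were called are in doubt.

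The 4 libraries held 202, 297, 306 and 251 barcodes for control, agrimoniin, erlotinib and combination, 1056 in all, far under the target in the labels. Their total UMI counts were 3656549, 5133188, 5301915 and 4050572. No barcode sequence was found in more than a single library.

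The plan made before the data were examined was to assign each barcode to a species at 90% of its UMIs. That rule left 0, 9, 7 and 23 human barcodes in control, agrimoniin, erlotinib and combination, and 0 mouse barcodes in all 4 libraries. The plan could not be followed, because every barcode held many UMIs of both species. After the data were seen, the human-gene UMIs of each barcode were therefore taken as its human part and the mouse-gene UMIs as its mouse part, and all values below come from these parts. A human part holds the RNA of PANC-1 cells and a mouse part that of host cells, and a part need not be a single cell. No doublet caller was run, since every barcode had 2 species, and doublets within a species were not removed.

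A part was kept with at least 500 UMIs, at least 250 genes and at most 25% mitochondrial UMIs. This kept 1013 human parts (193, 283, 292 and 245) and 1053 mouse parts (202, 297, 305 and 249). UMIs were summed over the kept parts of a library and scaled by their total to counts per 1e6 UMIs (CPM). The kept human parts held 2420470, 3690705, 3775711 and 3109510 UMIs.

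With 1 library per group there was no test across samples, and cells were not used as replicates. Folds are ratios of CPM with an exact 95% interval conditional on the sum of both counts. Log2 ratios used a pseudocount of 10 CPM, which understates the change of low genes. For a gene at 0 counts in a library, a floor of 3 counts in that library gives the fold as a bound, with the finite end of its exact interval beside it. For a gene list, the median log2 ratio was taken over members with a mean CPM of at least 10, with a 95% interval from 1000 Poisson redraws and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Shares have exact Clopper-Pearson 95% intervals. All intervals cover counting error only. Members of a list can change together, for example with the share of dividing cells, which neither these intervals nor the random lists measure.

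The human lists were glycolysis, lactate handling, hypoxia response, EGFR-MAPK output, EGFR family and ligands, S phase, G2/M phase, oxidative phosphorylation, pro-apoptotic genes, integrated stress and unfolded protein response, NRF2 targets, interferon response, MHC class I presentation, NF-kB and cytokine genes, mesenchymal genes, epithelial genes, cholesterol synthesis and dissociation stress. The mouse lists were pro-inflammatory macrophage genes, alternatively activated macrophage genes, MHC class II presentation, collagen and matrix, myofibroblast genes, inflammatory fibroblast genes, host glycolysis, host lactate handling and host interferon response. Postn is in both the collagen and the myofibroblast list.

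Genes were named by a fixed rule of size. For each treated library against control, these were the 10 human genes with the highest and the 10 with the lowest log2 ratio, among genes with a mean CPM of at least 20 and a UMI in at least 10% of parts of the library where the gene was higher. For the combination against each single drug, and for each mouse class with at least 20 parts in both libraries, 5 and 5 were named. Mitochondrial genes, ribosomal protein genes, clone-named genes and sex-linked marker genes were left out. EGFR, LDHA, LDHB and MKI67 were always named, and list members could be named as those with the largest absolute change. Gene positions are from GENCODE 29 (GRCh38), in which 34616 of the 36601 human identifiers were found.

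Mouse parts were clustered with scanpy 1.11.5 (2000 variable genes, 20 components, 15 neighbours, Leiden resolution 0.5). A cluster was given the name of a class, with "-like", from fixed marker lists when at least 3 markers were detected and its leading genes did not go against the name. The names were rebuilt here and are not the authors'.

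The only comparison with replicates was chosen after the data were seen. It set human genes of barcodes with a fibroblast-like mouse part against those with a macrophage-like mouse part, with UMIs summed per library and class and the 4 libraries as blocks. It used the quasi-likelihood test of edgeR 4.0.16 with TMM scaling, its expression filter and Benjamini-Hochberg adjustment at 0.05, and DESeq2 1.42.0 as an alternative. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.

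The fold intervals were tested on simulated counts at the depths of agrimoniin and control. Those counts were Poisson draws, which the intervals assume, so the test checks the calculation and not the spread of real libraries. The intervals held the true fold for 100% of 50 genes simulated at 0.5-fold, for 98% of 50 genes at each of 1.5-fold, 2-fold and 3-fold, and for 95.7% of 6972 unchanged genes. Of random lists of 15 unchanged genes, 5.5% had a percentile outside the central 95%, in a simulation whose genes varied independently. The edgeR comparison, tested on 10279 genes simulated at a common dispersion, found 80% of genes at 0.5-fold, 46% at 1.5-fold, 94% at 2-fold and 100% at 3-fold, and 5 of its 165 calls were false.

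Alternatives were other species thresholds, filters, pseudocounts, scalings, low-expression limits, weights per barcode, cluster resolutions and class rules, and a common minimum of mouse UMIs. Alternatives for named mouse genes and mouse lists were added after the data were seen.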

Results

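The series asked how agrimoniin, an ellagitannin from agrimony plants, and erlotinib, an inhibitor of the EGFR tyrosine kinase, alone and together act on pancreatic tumours, their proliferation, their lactic acid and their microenvironment. PANC-1 is a human pancreatic ductal adenocarcinoma line. Tumours grown from it in nude mice gave 1 library each for control, agrimoniin, erlotinib and combination, so no difference below has a replicate check, and each compares 2 libraries rather than 2 treatments. The series' design text names a compound, cyranin, where the sample labels give erlotinib, and the labels were followed. The 3 comparisons against control share that library, so a deviation of the control alone would appear in all of them.

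Human genes took 68.5% of UMIs in control, 73.9% in agrimoniin, 73.8% in erlotinib and 77.9% in combination. No barcode was of a single species. The human share per barcode ran from 28.2% to 94.1%. Median UMIs per barcode were 17241.5, 16793, 16532 and 15338 in that order, and median mitochondrial shares of human UMIs were 10.6%, 9.95%, 9.48% and 9.21%. The lowest mouse UMI total of a barcode was 2590 in control, 2086 in agrimoniin, 1567 in erlotinib and 1372 in combination. If barcodes were kept only above such a minimum, a higher minimum would lower the human share. The human shares are therefore not read as tumour content, and this was not tested. The summed human profiles were close, with Pearson correlations across 7172 genes from 0.982 to 0.987, although genes are not independent replicates. Log2 ratios to control had a standard deviation of 0.20 in agrimoniin, 0.22 in erlotinib and 0.22 in combination. Counting error alone would give 0.13, 0.13 and 0.14, so the intervals below understate the spread between libraries.

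**Figure D1:**
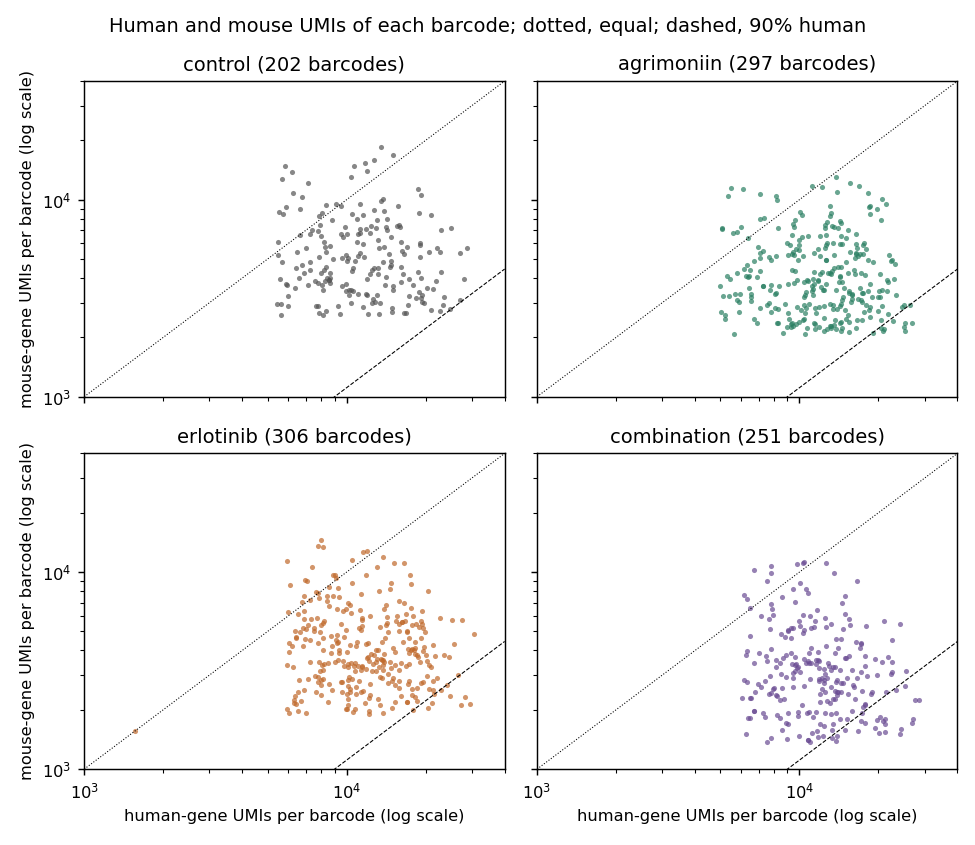
Human-gene UMIs (x, log scale) against mouse-gene UMIs (y, log scale) of each barcode in the 4 libraries, with lines at equal numbers and at 90% human. Every barcode holds both species, and 39 of 1056 lie at or beyond 90% human.

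The first comparison asks what agrimoniin alone did to the tumour cells. In the agrimoniin library, transcripts of the dividing cell were more abundant than in control, among them the replication helicase genes MCM4 and MCM6 and the mitotic genes CDC20, CDK1 and CCNB1. Heat-shock transcripts were lower, above all the strictly inducible chaperone gene HSPA6. DUSP6, the phosphatase gene that ERK signalling switches on and whose product dampens ERK, was higher. SNAI1, a transcription factor gene of epithelial-mesenchymal transition, and SOCS3, a feedback inhibitor gene of cytokine signalling, were lower.

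The S phase list had a median log2 ratio of 0.19 (95% interval 0.05 to 0.30), above 99.7% of random lists. With a pseudocount of 1 CPM its median was 0.33, and over members of at least 50 CPM it was 0.31. The G2/M phase list had a median of 0.21 (0.08 to 0.27), above all 10000 random lists. Random lists hold unrelated genes, so a differing share of dividing cells among the sampled parts would also move both lists. MKI67 itself, the common proliferation marker, was at 141 CPM against 136 in control, a ratio of 1.03 (0.899 to 1.19), so no difference in it was detectable at this depth. HSPA6 was 4.33-fold lower (3.35 to 5.65), at 21.9 CPM against 95.02. The dissociation stress list, which holds chaperone and immediate early genes, was lower at -0.19 (-0.25 to -0.14), under all but 0.07% of random lists. DUSP6 was 1.80-fold higher (1.62 to 2.01), at 334 CPM against 186. EGFR was at 160 CPM against 169, a ratio of 0.946 (0.833 to 1.08), the EGFR-MAPK output list had a median of 0.08 (-0.01 to 0.16), and EGFR family and ligands had -0.09 (-0.22 to 0.11). NF-kB and cytokine genes were higher, with a median of 0.24 (0.14 to 0.42), with the adhesion gene ICAM1 and the survival gene BIRC3 among them. CCL2 is in this median although mouse Ccl2 was higher too, at 2760 CPM in fibroblast-like parts against 907, and its reads may enter human CCL2. Without CCL2 the median was 0.22. Pro-apoptotic genes, BBC3 among them, had a median of -0.19 (-0.26 to 0.01), under all but 0.25% of random lists, with an interval that holds 0.

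The other genes named as highest were COL6A3, CTSV, NID1, CCN2, MEF2C, ULK2, ARF5, HMGA1 and POLD2. COL6A3 was 7.08-fold higher (4.42 to 12.0), but 21.5% of its UMIs came from 1 barcode, as did 32.7% of those of CTSV. NID1, a basement membrane gene, was 2.36-fold higher (2.06 to 2.71). The other lowest genes were MTRNR2L12, CLU, HMOX1, EFNA1, CROCC, IER5 and DLX2. MTRNR2L12 resembles mitochondrial ribosomal RNA, so its counts are uncertain, and CROCC had a log2 ratio of 0.03 in barcodes with at least 75% human UMIs against -0.70 over all barcodes. The median was 0.17 for NRF2 targets, 0.14 for interferon response, 0.07 for mesenchymal genes, 0.06 for cholesterol synthesis, 0.05 for integrated stress and unfolded protein response, 0.04 for MHC class I presentation, 0.03 for oxidative phosphorylation and -0.06 for epithelial genes. The median over all 9282 genes of the pool was 0.03.

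The comparison of erlotinib with control asks what blocking EGFR did. DUSP6 was lower, and so were the EGFR ligand gene EREG and the epithelial membrane gene EMP1. KLF4 and HMOX1, the haem oxygenase gene that oxidative stress switches on, were lower as well. Replication and mitosis genes such as PCNA, UHRF1, BIRC5 and CDK1 were higher than in control. IGFBP4, which encodes a binding protein of insulin-like growth factors, was the highest of the named genes.

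DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271) was 1.95-fold lower (1.69 to 2.25), at 95.1 CPM against 186. EREG was 2.31-fold lower (1.87 to 2.88). EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628), whose product the drug binds, was at 184 CPM against 169, a ratio of 1.09 (0.961 to 1.23). The EGFR-MAPK output list as a whole had a median of -0.06 (-0.15 to 0.06), with 6 members above 0, CCND1 among them, and 9 below, DUSP6, IER3 and MYC among them. In barcodes with at least 75% human UMIs that median was -0.23. The EGFR family and ligands list had a median of -0.18 (-0.28 to 0.02), and of 0.07 among barcodes with a mitochondrial share of at most 10%. The S phase median was 0.30 (0.18 to 0.43), above all random lists, and the G2/M median was 0.18 (0.06 to 0.25), above 99.9% of them. MKI67 was 1.18-fold higher (1.03 to 1.35). NF-kB and cytokine genes had a median of 0.20 (0.05 to 0.33), but of -0.11 among barcodes with a mitochondrial share of at most 10%.

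IGFBP4 was 2.91-fold higher (2.25 to 3.799) and the imprinted growth RNA H19 was 2.08-fold higher (1.96 to 2.22). The other highest genes were EGR4, ZNF90, PLEKHH2, C15orf48, KIFC1, RCAN1, FAM107B and MYL9, and the other lowest were RRAD, BMPR1B, CCDC173, OSR2 and MTRNR2L12. HSPA6 did not differ detectably from control, with a ratio of 1.06 (0.897 to 1.25), and the dissociation stress median was -0.03. Oxidative phosphorylation had a median of 0.12 (0.01 to 0.19), above 98.4% of random lists. Interferon response, with 5 measured members, had 0.25 (0.03 to 0.47), above 97.0% of them. The median was 0.12 for epithelial genes, 0.02 for cholesterol synthesis, -0.02 for integrated stress and unfolded protein response, -0.02 for NRF2 targets, -0.07 for mesenchymal genes and -0.09 for pro-apoptotic genes. MHC class I presentation sat at -0.00 (-0.11 to 0.10).

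The combination against control asks what both drugs did together. HSPA6 and HMOX1 were lower, and so was ZFAND2A, a heat-inducible gene of protein quality control. EREG was lower, as with each drug alone, but DUSP6 was higher, as with agrimoniin alone. Cell-cycle lists were lower than with erlotinib alone and not detectably different from agrimoniin alone. LOX, a collagen cross-linking gene that hypoxia induces, was higher, while the hypoxia genes NDRG1 and ANGPTL4 were lower.

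HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910) was 6.29-fold lower (4.58 to 8.80), HMOX1 was 3.62-fold lower (2.79 to 4.75), and ZFAND2A was 3.20-fold lower (2.502 to 4.13). For HMOX1, 23.6% of the UMIs of control came from 1 barcode. In each library human HMOX1 was higher beside macrophage-like than fibroblast-like mouse parts, at 133 against 65.6 CPM in control. Mouse reads may thus enter its counts, which was not tested. DUSP6 was 1.68-fold higher (1.502 to 1.88) and EREG was 2.23-fold lower (1.78 to 2.80), against 1.58-fold lower (1.30 to 1.93) with agrimoniin alone. EGFR was at 160 CPM against 169, a ratio of 0.948 (0.830 to 1.08). The EGFR family and ligands list was lower, at -0.26 (-0.47 to -0.06), under all but 0.33% of random lists, and the EGFR-MAPK output list was at -0.03 (-0.07 to 0.12), or -0.08 in barcodes with at least 75% human UMIs. The S phase median was 0.11 (-0.01 to 0.26) and the G2/M median was 0.07 (-0.01 to 0.15), and both intervals hold 0. MKI67 had a ratio of 1.05 (0.906 to 1.21). The mesenchymal list had a median of -0.18 (-0.29 to -0.01), but 6 of its 14 measured members were higher, CDH2 and TAGLN most, and none was lower by 1.5-fold in the combination. Its summed CPM was 7805 against 7636. The dissociation stress median was -0.25 (-0.31 to -0.17), under every random list. NF-kB and cytokine genes were at 0.24 (0.07 to 0.32) over all barcodes and at 0.01 in barcodes with at least 75% human UMIs.

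The highest genes were ZNF90, NID1, H19, CCDC74A, LOX, IGSF10, PCDH9, HEY1, IRX3 and CAMKK2, from 2.90-fold for ZNF90 to a log2 ratio of 0.73 for CAMKK2. The other lowest were MTRNR2L12, SNAI1, LRIF1, MEG8, CROCC and CCDC150, and CROCC went from -0.81 to 0.19 in barcodes with at least 75% human UMIs. The median was 0.15 for MHC class I presentation, 0.12 for interferon response, 0.08 for oxidative phosphorylation, 0.05 for epithelial genes, 0.01 for integrated stress and unfolded protein response, -0.04 for cholesterol synthesis, -0.06 for pro-apoptotic genes and -0.09 for NRF2 targets.

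**Figure D2:**
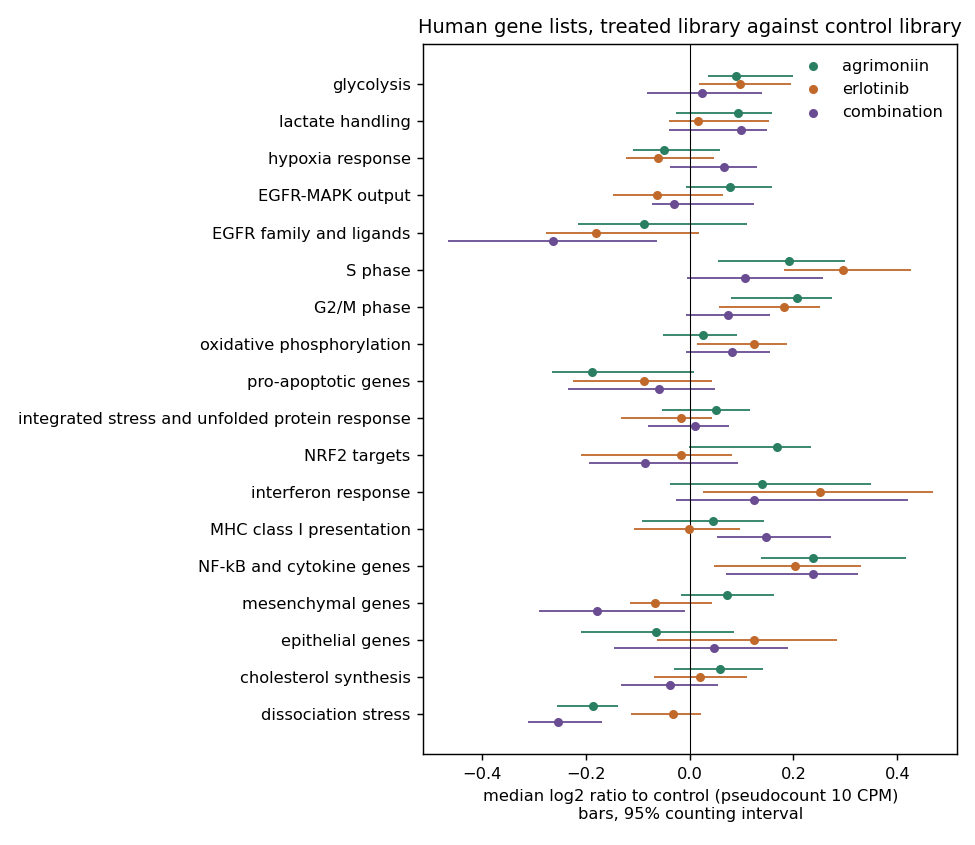
Median log2 ratio to control (x) of each human gene list in the agrimoniin, erlotinib and combination libraries, with 95% counting intervals as bars. The S phase medians are 0.19, 0.30 and 0.11 in that order.

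The combination was also set against each single drug. Against erlotinib, DUSP6 was 3.28-fold higher (2.90 to 3.71), which was the largest difference among the genes named as higher there, and the ERK feedback genes SPRY1 and SPRY2 were higher too. BMPR1B, NEDD9, CCDC173 and OSR2 were the other genes named as higher, and HSPA6, C15orf48, KRT80, NOTUM and ZFAND2A as lower. The S phase list was lower at -0.19 (-0.25 to -0.05), and the G2/M list at -0.11 (-0.19 to -0.06), which became 0.01 among barcodes with a mitochondrial share of at most 10%. MHC class I presentation was higher at 0.22 (0.08 to 0.28), with HLA-E and HLA-B higher and B2M lower. Against agrimoniin, the named genes were EFNA1, SAT1, CYP1B1, TMEM98 and ZNF90 as higher, and COL6A3, KRT80, PTHLH, ZFAND2A and HMOX1 as lower. Mesenchymal genes were lower at -0.24 (-0.33 to -0.11), with CALD1 and THBS1 in front, and so were EGFR family and ligands at -0.25 (-0.40 to -0.10) and NF-kB and cytokine genes at -0.23 (-0.31 to -0.07). The S phase list was at -0.06 (-0.14 to 0.08) and the G2/M list at -0.04 (-0.15 to 0.00), both within the range of random lists.

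Lactic acid is in the question of the series, and the list medians of the genes that make and move it differed little. LDHA (ENSG00000134333, chromosome 11, 18394388 to 18408425) encodes the enzyme subunit that turns pyruvate into lactate. It was not lower in any treated library. LDHA was at 726 CPM in control, 791 in agrimoniin, 878 in erlotinib and 778 in combination, ratios of 1.09 (1.03 to 1.16), 1.21 (1.14 to 1.28) and 1.07 (1.01 to 1.14). LDHB was at 326, 324, 358 and 325 CPM. The lactate handling list had medians of 0.09, 0.02 and 0.10, each with an interval that holds 0. The glycolysis list had medians of 0.09 (0.03 to 0.20), 0.10 (0.02 to 0.20) and 0.02 (-0.08 to 0.14), with GAPDH and ENO1 higher and the regulator gene PFKFB3 lower. Its summed CPM was higher in each treated library, at 4821 in agrimoniin, 4771 in erlotinib and 4709 in combination against 4141 in control. As a mean over barcodes the erlotinib glycolysis median was 0.20, and over members of at least 50 CPM that of the combination was 0.15. The lactate exporter gene SLC16A3 was lower in the combination, at 29.6 CPM against 40.1. The hypoxia response list had medians of -0.05, -0.06 and 0.07. Lactate itself was not measured.

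The host side bears on the microenvironment. Mouse parts formed macrophage-like, fibroblast-like, monocyte-like, endothelial-like and pericyte- or smooth muscle-like clusters, and no neutrophil-like cluster. Macrophage-like parts made up 42.6% of mouse parts in control (35.7 to 49.7), 47.8% in agrimoniin (42.0 to 53.7), 47.5% in erlotinib (41.8 to 53.3) and 40.2% in combination (34.0 to 46.5). Fibroblast-like parts made up 42.1% (35.2 to 49.2), 32.3% (27.04 to 37.97), 29.2% (24.1 to 34.6) and 36.5% (30.6 to 42.9). Monocyte-like parts, led by Ly6c2, made up 6.93% (3.84 to 11.4), 11.1% (7.77 to 15.2), 17.4% (13.3 to 22.1) and 14.9% (10.7 to 19.9). Endothelial-like parts made up 3.96%, 6.06%, 4.59% and 5.62%, and Il2rb and Kit also led their cluster. At a Leiden resolution of 1.0 there were 19 endothelial-like parts and 37 natural killer-like parts led by Gzma, Il2rb and Kit, so these shares may hold other cells in large part. Pericyte- or smooth muscle-like parts made up 4.46%, 2.69%, 1.31% and 2.81%.

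These shares depend on how classes were built and on the different lowest mouse UMI totals of the libraries. When each part was named by its marker counts, the monocyte-like shares were 0.495%, 2.02%, 0.984% and 2.81%, with control lowest again but the order of the treated libraries changed. These shares rest on only 1, 6, 3 and 7 parts. With a common minimum of mouse UMIs no cluster was named monocyte-like, so that share could not be read. Control was no longer lowest in endothelial-like parts at a Leiden resolution of 1.0, with 1.98% (4 parts) against 0.984% in erlotinib (3 parts) and 1.20% in combination (3 parts). At a Leiden resolution of 1.0 the fibroblast-like shares were 27.2%, 21.2%, 19.3% and 20.5%, and with a common minimum of mouse UMIs the macrophage-like shares were 19.3%, 31.1%, 24.0% and 26.8%, since some clusters lost their names. With that common minimum the fibroblast-like shares were 43.1% in control, 36.9% in agrimoniin, 33.7% in erlotinib and 41.8% in combination. The combination thus lay closer to control than without it.

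**Figure D3:**
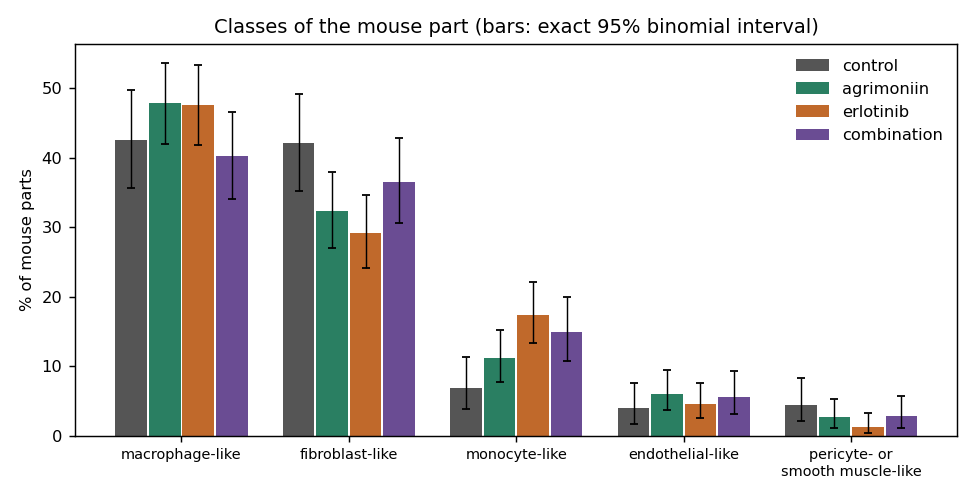
Share of mouse parts (y, %) in each class in the 4 libraries, with exact 95% binomial intervals as bars. Fibroblast-like shares run from 29.2% in erlotinib to 42.1% in control.

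Within macrophage-like parts, genes of alternatively activated, tissue-resident macrophages were higher with erlotinib and the combination. Lyve1 and the scavenger receptor gene Cd163 were in front, while Spp1 of the same list was lower. MHC class II presentation was lower beyond counting error in the combination only, through H2-Aa, H2-Ab1 and H2-DMb1. The inflammatory cytokine gene Tnf was also higher in the combination, so both programmes stood above control there.

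The alternatively activated list had medians of 0.07 (-0.28 to 0.42) in agrimoniin, 0.71 (0.46 to 0.92) in erlotinib and 1.16 (0.79 to 1.31) in combination, the last 2 above all random lists. The macrophage-like cluster led by Cbr2, Ccl8, Wfdc17 and Lyve1 held 5 parts in control and 18, 16 and 20 in the treated libraries, that led by Mmp12 and Arg1 held 56, 67, 87 and 46, and that led by Ccl3 and Il1b 25, 57, 42 and 34. Within the Mmp12-led cluster the alternatively activated medians were -0.16, 0.46 and 0.44, and within the Ccl3-led cluster 0.30, 0.28 and 0.34. The difference over the class may thus come in large part from the mix of clusters, although genes of the list also help to set the clusters. MHC class II presentation was at -0.13, -0.01 and -0.74 (-0.82 to -0.42), the combination under every random list, and at -0.69 and -0.28 within those 2 clusters of the combination. Pro-inflammatory macrophage genes were at 0.15, 0.10 and 0.31 (0.16 to 0.53). Host glycolysis was at -0.06, -0.26 and -0.05, host lactate handling at -0.20, -0.06 and -0.18, and host interferon response at 0.13, 0.04 and 0.18, the last at -0.43 and -0.08 within those clusters. In the combination, Ccl8, a monocyte attractant gene, was 5.54-fold higher (4.58 to 6.74), Wfdc17 6.78-fold (4.84 to 9.69) and Cxcl1 4.58-fold (3.23 to 6.62). Lpl, the lipoprotein lipase gene, was 8.73-fold lower (3.17 to 33.5) there. Lyve1 and Fam126b were the other highest genes of the combination, and Tpm3-rs7, Gdpd3, A930014D07Rik and Ddhd2 the other lowest. Single parts weigh on these folds, since 1 part gave 25.5% of the Ccl8 UMIs and 32.0% of the Wfdc17 UMIs in the combination, and 63.4% of the Cxcl1 UMIs and 30.95% of the Lpl UMIs in control. So does the mix of clusters, since within the Mmp12-led and Ccl3-led clusters the log2 ratios were 1.08 and 0.54 for Ccl8 against 2.44 over the class, 1.77 and 1.35 for Wfdc17 against 2.65, 3.57 and 1.54 for Cxcl1 against 2.09, and -1.94 and 0.00 for Lpl against -2.40. Lyve1 was at 1.92 and 0.00 within them against 2.33. In erlotinib, Npl, Hspb1, Kitl, Siglec1 and Pbx3 were the highest genes and Gdpd3, Hmgxb3, Inhba, Med29 and Egr2 the lowest, but 1 part gave 46.7% of the Hspb1 UMIs in erlotinib and 61.5% of the Egr2 UMIs in control. Within single clusters some were far closer to control, Siglec1 at 0.62 in the Ccl3-led cluster against 1.96 over the class, Pbx3 at 0.73 and Hspb1 at 0.84 in the Mmp12-led cluster against 1.77 and 2.49, and Egr2 at -0.66 and -0.33 in the Mmp12-led and Ccl3-led clusters against -1.62. Pbx3 and Hspb1 were further from control in the Ccl3-led cluster, at 3.18 and 3.59. In agrimoniin, Ighm, Ralgapa1, Fam126b, Vps72 and Wfdc17 were the highest, and Tpm3-rs7, Gdpd3, Gm11290, Dusp4 and H2-Q6 the lowest. In the Ccl3-led cluster Ralgapa1 was at -0.12 against 1.78 over the class, Wfdc17 at 0.55 against 1.60 and Gm11290 at -0.08 against -1.90. Ighm was at 1.22 in the Mmp12-led cluster against 1.89, and the other named genes stayed within counting error in both clusters. Tpm3-rs7, whose sequence resembles Tpm3, had 0 counts in agrimoniin against 46 in control, at least 22.4-fold lower against a floor of 3 counts, with an exact 95% limit of 17.5-fold.

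Within fibroblast-like parts, genes of inflammatory fibroblasts were higher in all 3 treated libraries, with the hyaluronan synthase gene Has1, Dpt, Ly6c1 and Ccl2 in front. Genes of contractile myofibroblasts, such as Tagln, Acta2 and Myl9, were lower with each single drug but hardly with the combination. Sparcl1, a matrix-associated gene, was far lower in agrimoniin and the combination. The cluster led by Grem1, Lrrc15 and Tagln held most of this class in control, erlotinib and combination, with 71, 54 and 55 parts, but not in agrimoniin, with 44. That led by Prg4, Mmp3 and Ptx3 had 14 in control and 52, 35 and 36 in agrimoniin, erlotinib and combination.

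The inflammatory fibroblast list had medians of 1.60 (1.36 to 1.76), 1.099 (0.96 to 1.25) and 1.07 (0.77 to 1.24) in agrimoniin, erlotinib and combination, all above every random list. Within the Grem1-led cluster alone they were 0.15, 0.57 and -0.20. Myofibroblast genes were at -0.77 (-0.91 to -0.68), -0.93 (-1.11 to -0.80) and -0.07 (-0.25 to -0.00), and at -0.07, -0.60 and 0.21 within that cluster. Host interferon response, with Rsad2 and Ifit1, was at 0.42, 0.80 and 0.35, against 0.00, 0.61 and -0.06 within it. Host glycolysis was at -0.45, -0.46 and 0.15, against 0.03, -0.28 and 0.39 within it. Collagen and matrix was at -0.49, -0.23 and -0.34, against -0.17, 0.13 and -0.19 within it, and host lactate handling was at 0.00, -0.09 and -0.09. Sparcl1 was 15.2-fold lower (10.8 to 22.2) in agrimoniin and 11.9-fold lower (8.28 to 17.7) in combination, and within that cluster its log2 ratios were -3.04 and -3.10.

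In agrimoniin the other named fibroblast-like genes were Mmp3, Tmem100, Prg4, Ptx3 and Lif as higher and Gzmd, Lmo7, Ecrg4 and Ctla2a as lower. Gzmd had 53 counts in control, 45.3% of them from 1 part, and 1 count in agrimoniin. Within the Grem1-led cluster the log2 ratios of the higher genes shrank, for Mmp3 to 0.79, Tmem100 to 0.00, Ptx3 to 0.25, Lif to 1.24 and Prg4 to 2.06, while those of the lower genes stayed within counting error. In erlotinib, Serpinb2, with 0 counts in control, was at least 27.5-fold higher against that floor (exact limit 21.8-fold), with 32.5% of its UMIs from 1 part, and Mmp3, H2-Eb1, C1qc and Prg4 were also higher, with 45.4% of the H2-Eb1 UMIs and 30.3% of the C1qc UMIs from 1 part. Within the Grem1-led cluster Serpinb2 had a log2 ratio of 1.79 against 3.87 over the class, Mmp3 1.79 against 3.15 and Prg4 1.67 against 2.61. In control 1 part gave 65.0% of the C1qc UMIs and 55.3% of the Prg4 UMIs. C1qc, a macrophage gene, had a UMI in 18.0% of those fibroblast-like parts (median 5698 mouse UMIs) and in 8.24% in control (median 6229), against 97.9% of macrophage-like parts in erlotinib (median 3631), so macrophage RNA was present in them. C1qc was at 33.2 CPM in control, 130 in agrimoniin, 270 in erlotinib and 19.7 in combination, and within the Grem1-led cluster of erlotinib C1qc and H2-Eb1 had log2 ratios of 3.90 and 3.72, so other lists there, host interferon response among them, may hold RNA of other cells too. Col10a1, Mgp, Thbs4, Angptl1 and Mmd were lower, with 42.3% of the Col10a1 UMIs of control from 1 part. In combination, Cxcl10, an interferon-induced chemokine gene, was 7.60-fold higher (5.57 to 10.5), but 35.6% of its UMIs came from 1 part. Mmp3, Prg4, F3 and Mmp10 were also higher, although Prg4 had a log2 ratio of 0.01 within the Grem1-led cluster against 2.26 over the class, and Tpm3-rs7, Spp1, Mgp and Ak1 were lower. Spp1, the osteopontin gene, was 4.32-fold lower (3.67 to 5.11).

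**Figure D4:**
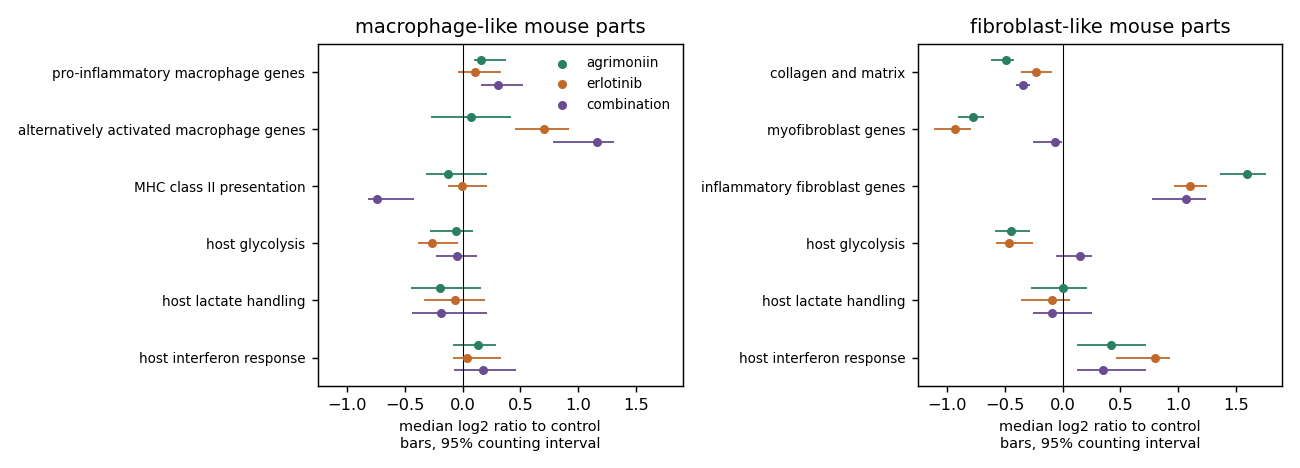
Median log2 ratio to control (x) of each mouse gene list in macrophage-like (left) and fibroblast-like (right) parts of the 3 treated libraries, with 95% counting intervals as bars. The inflammatory fibroblast medians are 1.60, 1.099 and 1.07.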

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

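Of the tests in this part, 4 were chosen only after the result was seen, namely those of Col1a2, of the lowest mouse UMI totals, of the mouse heat-shock genes and of the fibroblast-like clusters. The patterns themselves were picked from the same data. A drop of myofibroblast genes had been picked first and was set aside once the combination gave -0.07.

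The differences of cell-cycle genes between libraries with and without agrimoniin had opposite signs without and with erlotinib. The S phase median was 0.19 for agrimoniin against control and -0.19 for the combination against erlotinib, a difference of -0.38. Against control, S phase medians were 0.19 in agrimoniin, 0.30 in erlotinib and 0.11 (-0.01 to 0.26) in combination. The negative value thus goes with the erlotinib library being the highest. The G2/M median was 0.21 without and -0.11 with erlotinib, a difference of -0.32, but the second value became 0.01 among barcodes with a mitochondrial share of at most 10%. For erlotinib, the median of NF-kB and cytokine genes was 0.20 against control and -0.23 for the combination against agrimoniin, a difference of -0.44. Among barcodes with a mitochondrial share of at most 10% the first of these was -0.11, so the opposite signs did not hold there. With 1 library per group, none of these 3 differences could be tested, and each was not tested.

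Every barcode held many UMIs of both species. Free mouse RNA alone is argued against, because 42.0% of 1053 mouse parts had no UMI of the abundant fibroblast gene Col1a2, while a common mouse profile at the same depths would give 9.64e-05%. A further candidate explanation is that only barcodes passing a minimum in both species were deposited, as droplets with both a human and a mouse cell would. The share of barcodes within 1.1 times the second lowest mouse UMI total was 6.93% in control, 8.08% in agrimoniin, 4.58% in erlotinib and 5.18% in combination, with 1.49%, 2.02%, 1.31% and 1.99% at the upper end. For human UMI totals the shares at the lower end were 7.43%, 3.70%, 5.56% and 6.77% in that order. Those at the upper end were 1.49%, 2.02%, 1.31% and 1.99%. For both species, each library thus had more barcodes at the lower end than at the upper end. For mouse totals erlotinib missed the share of 5%, which was set for all libraries after the data were seen. This explanation therefore stays open, and no biological explanation was tested.

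Heat-shock genes were lower in human UMIs of agrimoniin and combination than of control. Mouse reads assigned to human genes are argued against, since the median over the 6 genes in the combination was -0.50 in barcodes with at least 75% human UMIs and -0.38 over all barcodes. The median over the same-named mouse genes was lower too, at -0.38 in agrimoniin and -0.73 in combination, and -0.03 in erlotinib. In agrimoniin, however, Hspa1b was higher, at 1647 CPM against 1557, and Dnajb1 was nearly unchanged in both, at 276 CPM in each against 285. The lower mouse medians fit a change in the whole suspension, which may come from the handling of each tumour or from a drug effect on tumour and host alike. Handling and drug effect cannot be separated with 1 tumour suspension per group. The mouse medians also pool classes whose shares differ between libraries. In control, Hspb1 was at 741 CPM over all mouse parts but at 10.4 CPM in macrophage-like parts. The mix of classes, or human reads assigned to mouse genes, may thus lower these medians too, and neither was tested.

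Inflammatory fibroblast genes were higher in fibroblast-like mouse parts of all 3 treated libraries. A higher minimum of mouse UMIs in control is argued against, since with a common minimum the lowest of the 3 medians was 1.08, and so is free RNA from other mouse cells, since macrophage-like parts had medians of 0.24 (up to 0.40) in agrimoniin, 0.23 (up to 0.43) in erlotinib and 0.030 (up to 0.20) in combination, against 1.60, 1.099 and 1.07 in fibroblast-like parts. With the genes of the list left out of the clustering, the medians within the fibroblast-like cluster that held most control parts were 0.17 in agrimoniin, 0.57 (0.13 to 0.74) in erlotinib and -0.20 in combination. Within the other cluster, with 14 parts in control, they were 0.27 (-0.03 to 0.66), -0.24 (-0.47 to 0.12) and 0.08 (-0.35 to 0.59). A different mix of the 2 fibroblast-like clusters may therefore account for most of the pattern, and in erlotinib the 2 clusters had opposite signs, although clusters are set partly by genes that vary with the list. Whether the treatment or the sampling of each tumour set that mix stays open and was not tested.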

How the results depend on the processing

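Of the alternatives named here, the common minimum of mouse UMIs, the single clusters, the list without CCL2, the 75% human barcodes for single genes and all settings of the edgeR test were chosen after the data were seen. Where no cause is given below, the cause was not tested. A value is called reversed here only if its difference was beyond random lists or counting error in the main analysis and its sign changed.

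Of 150 values of the main human lists under alternatives, 143 stayed within counting error, 143 kept their sign and none reversed. These include 15 values from leaving out barcodes over 3 times the median UMIs, which removed none. Another 15 are from TMM scaling, whose factors of 0.993 to 1.005 could change little. The 740 values below hold 75 of each kind. A pseudocount of 1 CPM moved S phase to 0.33 in agrimoniin and 0.43 in erlotinib. Members of at least 50 CPM gave 0.31 for S phase in agrimoniin and 0.15 for glycolysis in combination. A mean over barcodes gave 0.20 for glycolysis in erlotinib. Barcodes with at least 75% human UMIs gave -0.23 for EGFR-MAPK output in erlotinib and -0.076 in combination. Of 740 values of the other human comparisons and lists, 685 kept their sign and 3 reversed, all at a mitochondrial share of at most 10%: EGFR family and ligands in erlotinib (0.075), NF-kB and cytokine genes in erlotinib (-0.11) and G2/M in combination against erlotinib (0.0065). That filter left 94 of 193 human parts in control. Of 400 values of named human genes, 354 stayed within counting error, 388 kept their sign and 2 reversed. Both reversals were for CROCC in barcodes with at least 75% human UMIs (0.027 in agrimoniin, 0.19 in combination). In those barcodes, 66 of 193 human parts in control, 26 other values moved beyond counting error and 72 did not. With a pseudocount of 1 CPM 17 moved and 83 did not.

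Within the Grem1-led fibroblast-like cluster, host glycolysis in agrimoniin (0.029), inflammatory fibroblast genes in combination (-0.20) and host interferon response in combination (-0.061) reversed. Collagen and matrix in erlotinib (0.13 against -0.23) and myofibroblast genes in combination (0.21 against -0.067) also changed sign there. Of 30 named genes there, 16 moved beyond counting error, Tmem100 in agrimoniin to 0.00 and Prg4 in combination to 0.0078. Within the macrophage-like cluster led by Ccl3, Ralgapa1 in agrimoniin (-0.12), host interferon response in combination against agrimoniin (-0.20) and alternatively activated genes in combination against erlotinib (-0.11) reversed, the last also within that led by Mmp12 (-0.0041). Of 330 values of mouse lists 287 kept their sign, and of 330 values of named mouse genes 326.

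With a common minimum of mouse UMIs, macrophage-like shares were 19.3%, 31.1%, 24.0% and 26.8% in control, agrimoniin, erlotinib and combination, because a cluster of 250 parts lost its name, and no cluster was monocyte-like. At a Leiden resolution of 1.0, fibroblast-like shares were 27.2%, 21.2%, 19.3% and 20.5%, because clusters of 74 and 57 parts had no name. At that resolution 37 parts became natural killer-like, and endothelial-like shares were 1.98%, 3.03%, 0.984% and 1.20%. By marker counts these were 1.98%, 2.02%, 0.656% and 1.20%, and with the common minimum 1.98%, 2.05%, 0.813% and 0.654%, so erlotinib and combination lay below control in all 3. These shares rest on 4 parts in control and 1 to 3 in erlotinib and combination, so their order cannot be read. The 3 settings are not independent, since they use the same barcodes.

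The edgeR test of human genes by class of the mouse part called 1 gene, 13 with no filter beyond 1 count, 0 with no replicate block and 0 with DESeq2. Leaving out each library in turn gave 0 to 2, with 0 without erlotinib. The block paired the 2 class sums of each library. Between treatments no paired analysis was possible, because each group has 1 library.

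Assignment at 95% human UMIs left no barcodes and was not run. Leaving out barcodes over 3 times the median UMIs removed none, so it says nothing. Scaling by TMM moved no human list beyond its counting error.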

Other observations

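All tests in this part were chosen after the data were seen.

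Barcodes with both species allow a test of whether human genes differ with the kind of host cell in the same barcode. The quasi-likelihood test of edgeR, with the 4 libraries as blocks, called 1 of 10279 human genes. That gene was CCL2, which encodes a monocyte-attracting chemokine, at a log2 difference of 1.59 (SE 0.21, adjusted p 0.000111), higher beside fibroblast-like than macrophage-like mouse parts in 4 of 4 libraries. The called share was 0.00973% of tested genes. Among these barcodes, this argues against a 2-fold or larger difference in at least 1% of human genes, since the test found 94% of genes simulated at 2-fold and 80% at 0.5-fold. That simulation gave all genes a common dispersion, so it may overstate the share found among more variable genes. If droplets caught a human and a mouse cell by chance at loading, no difference would arise whatever the state of the tumour. The test therefore cannot tell whether human cells differ with their host neighbours in the tumour. At an unadjusted p under 0.05 there were 656 genes, and DESeq2 called 0 with 94 at that level. Without the erlotinib library the count was 0, and without control or without combination it was 2. Of the 8 splits, 6 gave as many called genes, with 4 as the highest of the others, and 8 splits are too few for a share under 0.05. Mouse Ccl2 was also higher in fibroblast-like parts, at 907 to 2760 CPM against 288 to 763, so mouse reads assigned to human CCL2 may account for the call, and this was not tested.

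RPS16, ZFP36 and PSMC4 were among the most abundant human transcripts and lie near each other on chromosome 19. Set against the mouse gene of the same name in the same barcodes, human RPS16 was at 16224 against 1117 CPM, ZFP36 at 7447 against 2691 and PSMC4 at 2218 against 44.8. The 17 other genes from 38915266 to 39846414 (GRCh38) had a median human over mouse log2 ratio of 3.11, or 8.62-fold, against 0.22 over 9528 genes. FBL, MED29 and PAF1 were among them. This median stood at a percentile of 99.97 among 9176 windows of as many neighbouring genes, which is consistent with raised dosage of this stretch in PANC-1. The test was first run with the 3 genes included and repeated without them once that result was seen. Mouse parts are other cell types and no DNA was measured, so a difference between cell types stays open.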
